A study of Mus musculus with 2 samples.

How the data were processed

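Gene expression was measured on Affymetrix Mouse Genome 430 2.0 arrays, a design that reads each transcript with 1 or more probe sets, in germinal center (GC) B cells sorted from the draining lymph nodes of mixed bone marrow chimeras. Per the labels, lethally irradiated wild-type CD45.1 mice had received a mixture of STAT6-deficient (CD45.2) and wild-type (CD45.1) marrow. They were infected 8 weeks later with 500 larvae of Nippostrongylus brasiliensis, a nematode that elicits a type 2 response. Nodes of 5 chimeras were pooled at day 14, and GC B cells (B220+ CD38lo GL-7hi) were sorted into a CD45.2 and a CD45.1 fraction. Each fraction gave 1 array, labelled from 200 ng of total RNA, so the groups hold 1 sample each. The group of each array was taken from its title. The genotype field of the labels reads wild type for both samples, against the title, the source name and the sorted fraction. For both arrays the labels' protocol names a whole-transcript sense labelling kit, which does not match this array, a 3' expression design made for antisense target; which labelling was used is not settled by the sources used here.

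The authors deposited RMA signals per probe set, processed with Affymetrix Expression Console per the submitters' processing notes. A linear-scale table and a table of log2 values were deposited, and the log2 of the first differed from the second by at most 5.53e-06. Which arrays were normalized together, and the versions of the software, are not given in the sources used here. Gene symbols, Entrez identifiers and alignments came from the annotation columns of the deposited table, which name genome build NCBI 37. The reference table used here is of another assembly and served only to update symbols, so exon, intron and UTR positions were not used here.

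Of 45101 probe sets, 37592 carried 1 gene symbol, 1467 several and 6042 none. The 64 array control sets were kept apart. The remaining 37579 sets with 1 symbol stood for 20660 genes after symbols were updated through the Entrez identifier, which matched for 34316 sets and changed the symbol of 4285. A gene was represented by its probe set with the higher mean over both arrays, and sets with several symbols were not assigned to a gene. Differences are log2 values of the STAT6ko array minus those of the wild-type array. Genes entered the counts if the brighter array was at or above the median of all these sets, a log2 signal of 1.44, which left 15937 genes. The threshold was 2-fold. With 1 array per group no spread between samples could be estimated, no test between groups was possible and no p-value is given for any gene or list. For the same reason every value below has no replicate error.

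The precision of an array value is limited by the number of arrays. A background limit was therefore set on each array, chosen after seeing the data, from 80 probe sets of olfactory and vomeronasal receptor genes, which serve chemosensory neurons. A probe set was called above background where it exceeded the highest of these 80 sets on the same array, 2.08 on the wild-type array and 3.51 on the STAT6ko array. Counts of genes and list members above background use the chosen probe set of each gene, and a list member or named gene with another set above the limit is named as such. Where a gene was above background on the wild-type array only, its ratio is given as a lower bound, the wild-type signal over the STAT6ko background limit.

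Before the data were examined, 23 gene lists, the 2-fold threshold, the expression floor, the alternatives and the rule for naming genes were fixed. The rule names Stat6 and Ptprc, the 12 genes with the largest difference in each direction (predicted genes, clones and receptor segments left out, 447 of the genes counted as brighter on the STAT6ko array and 159 of those counted as dimmer) and up to 4 members of each list with the largest absolute difference. In lists of other cell types it also names the members of highest level. A few genes that the rule names are not reported here. Further genes named below were chosen after their values were seen. Each list's median difference was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. The procedure was tested on simulated data of all 20660 genes, made from the wild-type array with noise and 200 altered genes of higher level. It called 98% of the 100 genes altered by 1.5 on the log2 scale, 100% of the 100 altered by 2 and 0.073% of the unaltered ones, and it placed a list of 20 lowered genes at percentile 0 and a list of 20 unaltered genes at percentile 21. The simulated noise had an SD of 0.3, whereas the differences of the background probe sets between the real arrays had an SD of 0.66. These rates therefore describe a second array of full signal and are not the error rates of this comparison. The alternatives were no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, the mean over a gene's probe sets, quantile normalization, median centring, removal of an intensity trend by loess with a span of 0.3, a pseudocount of 32 on the linear scale, and the second deposited table. After quantile normalization the probe set of each gene was chosen anew by its mean over both arrays. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.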

Results

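The series compared the transcriptome of STAT6-deficient and wild-type GC B cells that had developed side by side in the same infected mice, and its title places the question in the B cell's own need for STAT6, the transcription factor that transmits interleukin-4 and interleukin-13 signals. The data are 2 arrays, 1 from the STAT6ko (CD45.2) fraction and 1 from the wild-type (CD45.1) fraction of the same pool. The wild-type array carried a GC B cell profile, with Bcl6, Mki67, the MHC class II genes and ribosomal protein genes far above background. The STAT6ko array carried almost no mouse transcript signal. On it 534 of 45037 mouse probe sets (1.19%) exceeded the highest of the 80 background probe sets, against 11343 (25.2%) on the wild-type array, where exchangeable background values would give 1.23%. The difference between the arrays is therefore described below as a difference between arrays and gives no measure of the effect of STAT6 on these cells. Whether these STAT6ko values are the ones the study analysed is not given in the sources used here.

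The transcripts found in nearly every cell showed the loss most plainly. Actb, which encodes the cytoskeletal protein beta-actin, had a log2 signal of 11.18 on the wild-type array and 2.04 on the STAT6ko array. The 3 Gapdh control sets, which read a glycolytic enzyme, had a median of 8.43 and 1.87, and the 3 sets for 18S ribosomal RNA a median of 7.31 and 1.94. Of the 24 poly-A control sets, which read bacterial transcripts usually added to the RNA before labelling, all lay between 9.88 and 13.36 on the wild-type array. On the STAT6ko array their median was 1.66 and 2 of the 24 were above background. The 18 hybridization control sets, which read labelled targets added after the labelling, were bright on both arrays, with a median of 12.10 on the STAT6ko array and 10.47 on the wild-type array, and all 18 were brighter on the STAT6ko array by between 0.16 and 2.89 on the log2 scale. The 3 sets for trpn, a bacterial gene, were at or below 1.59 on both arrays.

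**Figure D1:**
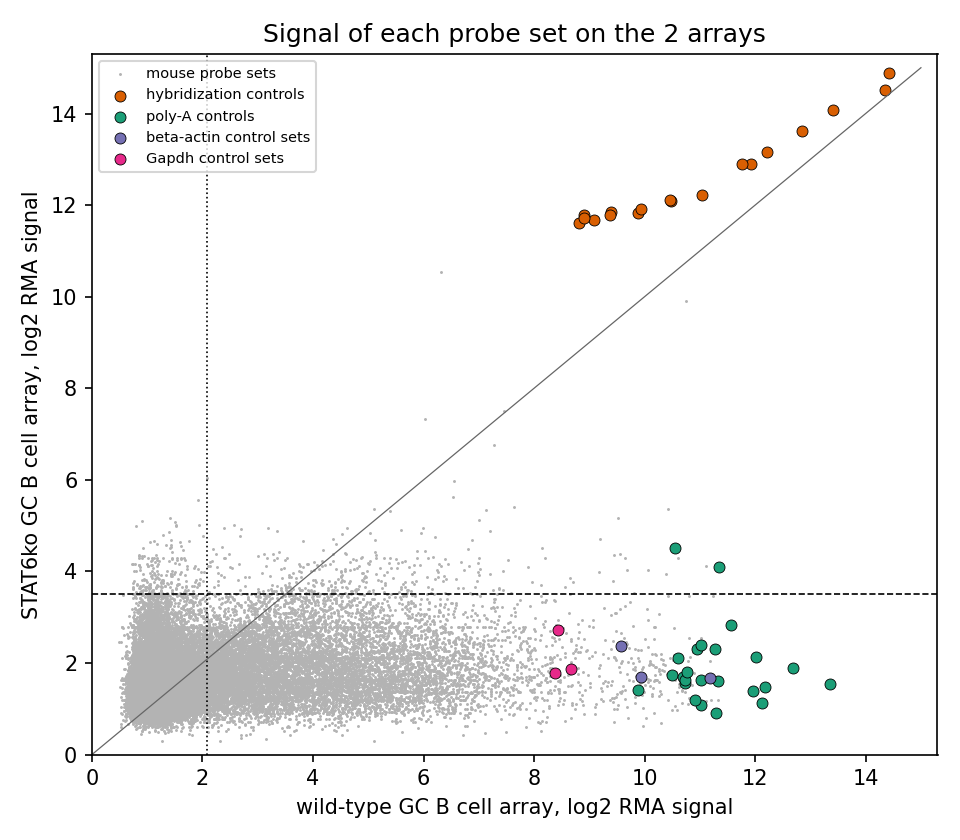
Log2 RMA signal of every probe set on the wild-type array (x axis) and the STAT6ko array (y axis), with control probe sets coloured by kind. The dotted and dashed lines mark the highest background probe set of the wild-type array (2.08) and the STAT6ko array (3.51), and the diagonal marks equal signal. The hybridization controls are bright on both arrays, whereas the 24 poly-A controls and the actin and Gapdh sets are bright on the wild-type array alone, with 2 poly-A sets above the STAT6ko line.

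The targeted gene was read by 2 probe sets. Stat6 lies on chromosome 10, and the brighter set (aligned to positions 127083967 to 127098043 of the plus strand in NCBI 37) had a log2 signal of 2.62 on the wild-type array and 1.35 on the STAT6ko array, a difference of -1.27. The other set (positions 127080226 to 127097459) read 1.56 and 1.54, below background on both arrays. Which exons the deletion removed is not given in the sources used here. Neither Stat6 set was above background on the STAT6ko array, and the wild-type signal lay under the 3.51 limit of that array, so no bound on the ratio can be given and the Stat6 signal does not check the labels. Ptprc, the gene of the CD45 allotypes used for sorting (chromosome 1, positions 139959991 to 140071882 of the minus strand), read 9.54 on the wild-type array and 2.44 on the STAT6ko array, at least 65.0-fold dimmer on the second, although both fractions were sorted as CD45-positive. A second Ptprc set (positions 140068537 to 140068860) read 1.71 and 1.20, not above background on either array, and the difference over both sets was -3.80.

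At the 2-fold threshold 4956 of 15937 genes were dimmer and 1928 brighter on the STAT6ko array. Quantile normalization of the arrays, after which the probe set of each gene was chosen anew, gave 2877 dimmer and 4225 brighter. Removal of the intensity trend gave 2256 dimmer and 2705 brighter, and a pseudocount of 32 gave 1495 and 3. Of the 4956 dimmer genes 111 were above background on the STAT6ko array, and of the 1928 brighter genes 169 were. Across the 20660 genes, which are not independent replicates, the difference followed the wild-type level with a Pearson correlation of -0.92, and the values of the 2 arrays correlated at r = 0.27 (Spearman 0.29). The first correlation is largely built in, because the difference subtracts the wild-type value. Over mouse probe sets the wild-type values also varied more (SD 1.53) than the STAT6ko values (SD 0.60). The STAT6ko median was 1.36 in the lowest twentieth of mouse probe sets ranked by wild-type signal, 1.85 in bin 17 of 20 and 1.85 in bin 19, while the wild-type medians of these bins were 0.78, 2.89 and 4.74.

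The 12 genes with the largest differences toward the wild-type array were abundant transcripts of most cells. They comprised the ribosomal protein genes Rpl37a, Rplp0, Rpl23a, Rps4x, Rplp2, Rpl19, Rps27 and Rps20, the translation elongation factor Eef1a1, Tpt1, Actb and Tmsb4x, which encodes the actin-binding protein thymosin beta 4. Tmsb4x read 11.20 against 1.19 and Eef1a1 10.78 against 1.11, which puts them at least 206-fold and 154-fold dimmer on the STAT6ko array. Of the 24 measured cytosolic ribosomal protein genes 23 were above background on the wild-type array and 3, Rpl7, Rps9 and Rps24, on the STAT6ko array. The median of the list was 9.78 on the wild-type array and 1.63 on the other.

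The 12 genes with the largest differences toward the STAT6ko array were Atox1, Tfpt, Nradd, Srd5a1, Zfp709, Sgsm3, Cdh8, Eif4e, Entpd8, Atf7, Tmem88b and Stx17. Atox1, which encodes a copper chaperone, read 10.55 on the STAT6ko array and 6.31 on the wild-type array, and its difference was -0.01 when all its probe sets were averaged. Eif4e, the cap-binding translation factor, read 5.01 and 1.52, and its difference was -0.19 over all its probe sets. Of these 12 probe sets, that of Atox1 was the only one above background on the wild-type array, but another set was above it there for Eif4e (4.59) and for Tfpt (2.32).

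The genes that respond to interleukin-4 through STAT6 in B cells were the list closest to the study's question. On the wild-type array 12 of its 18 measured members were above background. They included H2-Aa (10.60), H2-Eb1 (8.36), H2-Ab1 (8.02), Cd72 and Bcl6 (6.53), the transcriptional repressor that directs the GC program. Fcer2a, the low-affinity IgE receptor CD23, read 4.70, and Il4ra, the interleukin-4 receptor alpha chain, read 3.79. Cish, Socs1, Gfi1, Ccl17, Ccl22 and Il13ra1 were not above background. On the STAT6ko array H2-Aa alone was above background (4.29), and Bcl6 (1.36), Fcer2a (1.06) and Il4ra (1.44) were not. The list's median difference was -2.83, at percentile 1.19 of matched random lists, and it was -0.26 after removal of the intensity trend. The corresponding lists for the GC program (percentile 0.070), the cell cycle (0.72), immunoglobulin constant regions (1.54) and ribosomal proteins (0) also lay outside the central 95% of random lists, as did the sex-linked list described last, 6 of 23 in all. The remaining lists lay between percentile 4 (MHC class II) and percentile 87.5 (macrophage markers), and these medians describe the 2 arrays only. The difference followed the wild-type level (r = -0.92), and matching on the mean of both arrays did not remove this. For example, the ribosomal protein list had a median difference of -8.09, against a median of -3.98 over its matched random lists. These percentiles therefore cannot show a drop particular to STAT6 targets.

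The wild-type array showed the GC identity of the sorted cells in detail. Of the 22 measured genes of the GC B cell program 20 were above background, among them Pou2af1 (9.02) and Spib (7.89), transcriptional regulators of B cells, Bach2 (6.73) and Rgs13 (6.72), a regulator of chemokine receptor signalling. Pax5 and Mybl1 were not above background. All 15 dark zone genes were above background, including Cxcr4 (6.60), the chemokine receptor of dark zone cells, and Ccnb2 (5.95). Of the 20 measured light zone and activation genes 18 were, including Cd83 (6.94), Nfkbia (6.76) and Slamf1 (5.43). On the STAT6ko array Foxo1 (3.95, against 5.14 on the wild-type array) was the only member of these 3 lists above background. Among the bounds, Pou2af1 was at least 45.5-fold and Cd83 at least 10.7-fold dimmer there.

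Of the 27 cell cycle genes 25 were above background on the wild-type array, with Pcna (8.37), the DNA polymerase clamp, Mki67 (7.91), Rrm2 (7.39), a subunit of ribonucleotide reductase, and Ccna2 (6.75) as the members with the largest differences. Mcm3 and Tyms were not above background. No cell cycle gene was above background on the STAT6ko array, where Pcna read 1.51 and Mki67 1.88.

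Antigen presentation genes were likewise detected on the wild-type array, with 13 of the 14 measured MHC class II and costimulation genes above background and Cd80 (0.87) below it. Cd74, the invariant chain, read 8.80 there and 1.76 on the STAT6ko array, and H2-Ob 7.70 and 1.96. H2-Aa and Ctss, a lysosomal protease that trims the invariant chain, were above background on the STAT6ko array too, at 4.29 and 4.02. The differences of H2-Aa and H2-Ab1 changed sign to 2.20 and 0.64 after removal of the intensity trend.

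Genes of plasma cells were detected in part. Of 18 measured members 12 were above background on the wild-type array, including Jchain (8.47) and Mzb1 (8.33), which serve antibody assembly, Xbp1 (6.50) and Ssr4 (6.19), whereas Prdm1 (1.60) and Sdc1 (1.37) were not. The median difference of this list, -1.35, turned to 0.05 after quantile normalization and 0.34 after removal of the trend. Among naive and memory B cell genes 12 of 19 were above background, with Ltb at 8.76, Cr2 at 6.78, Nt5e at 3.33 and Cd38, low on the sorted cells by gate, at 3.69. The 3 measured immunoglobulin constant region genes were all above background, with Ighm at 8.32, the set annotated Ighg at 7.75 and Ighg3 at 4.51. Of the plasma cell list Sec11c (4.26) was above background on the STAT6ko array, and of the other lists of this paragraph no member was.

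In the STAT and JAK family 7 of 11 members were above background on the wild-type array, including Jak1 (6.91), Jak2 (4.97), Stat3 (4.54) and Stat5b (3.60). Of the cytokine receptor genes 11 of 22 were, including Tnfrsf13c, the receptor of the survival factor BAFF (7.84), Tgfbr2 (6.48), Tnfrsf13b (5.58) and Il2rg, the common gamma chain (5.29). Of the 19 measured apoptosis and survival genes 11 were, including Mcl1 (7.33), an antiapoptotic protein on which GC B cells depend, Bid (5.78) and Casp8 (5.07). On the STAT6ko array Bcl2 (3.80, against 1.69 on the wild-type array) and Bcl2l11 (3.58, against 5.09) were above background. The interferon response list had 9 of 22 members above background (16 at the 95th percentile of the background sets), with Irf1 at 4.39 and Isg20 at 3.36. On the STAT6ko array no chosen probe set of the STAT and JAK, cytokine receptor or interferon lists was above background, but another Stat3 set was, at 4.12. On the wild-type array another Stat5a set was, at 2.30.

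Among markers of other cell types on the wild-type array, 0 of the 13 measured follicular dendritic and stromal cell markers were above background (3 at the 95th percentile of the background sets), with Ccl19 at 1.03, Col1a2 at 0.99, Cxcl13 at 1.06 and Pecam1 at 1.86. Of 7 red cell markers 1 was, Eraf at 2.38, and Slc4a1, Car1 and Alas2 were not. Of 17 macrophage and monocyte markers 2 were (5 at the 95th percentile), Apoe at 5.41 and Mpeg1 at 3.84, and of 9 dendritic cell markers Flt3 at 3.75 and Itgax at 2.65. Of 16 granulocyte and mast cell markers 5 were, led by Cpa3, a mast cell protease, at 4.83. Among all genes 33.9% were above background on the wild-type array, so a count of this kind does not by itself show such cells. Of 23 T cell markers 12 were, including Lck at 6.26, the set annotated Tcrb-J at 5.44, Cd3d at 4.96 and Cd2 at 4.40. Of 12 markers of NK cells and innate lymphocytes 10 were, including Gzma at 4.77, Klrd1 at 4.21, Gzmb at 3.99 and Eomes at 3.52. Prf1 (1.76) and Klrb1c (1.35) were not, and Gata3 (2.14) and Nkg7 (2.21) lay close to the 2.08 limit. The source of these NK and innate lymphocyte transcripts was not tested separately. The early response genes of tissue handling had 8 of 16 members above background, with Egr1 at 5.70, Dnajb1 at 5.53, Hsph1 at 5.30 and Jund at 5.06. Members not above background included Fos (1.04), Jun (1.12), Atf3 (1.49) and Hspa1a (0.89), and Egr1 is also on the light zone list. On the STAT6ko array Lyz2 (3.99), a macrophage and granulocyte lysozyme, was the only member of these lists whose chosen probe set was above background, and another set annotated Tcrb-J was, at 3.69. On the wild-type array another Zap70 set was, at 2.57. Other members read higher there than on the wild-type array without passing its limit, for example Cd68 (2.93 and 1.10), Xcr1 (2.97 and 1.03), Camp (3.39 and 1.80) and Ccl19 (2.79 and 1.03).

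**Figure D2:**
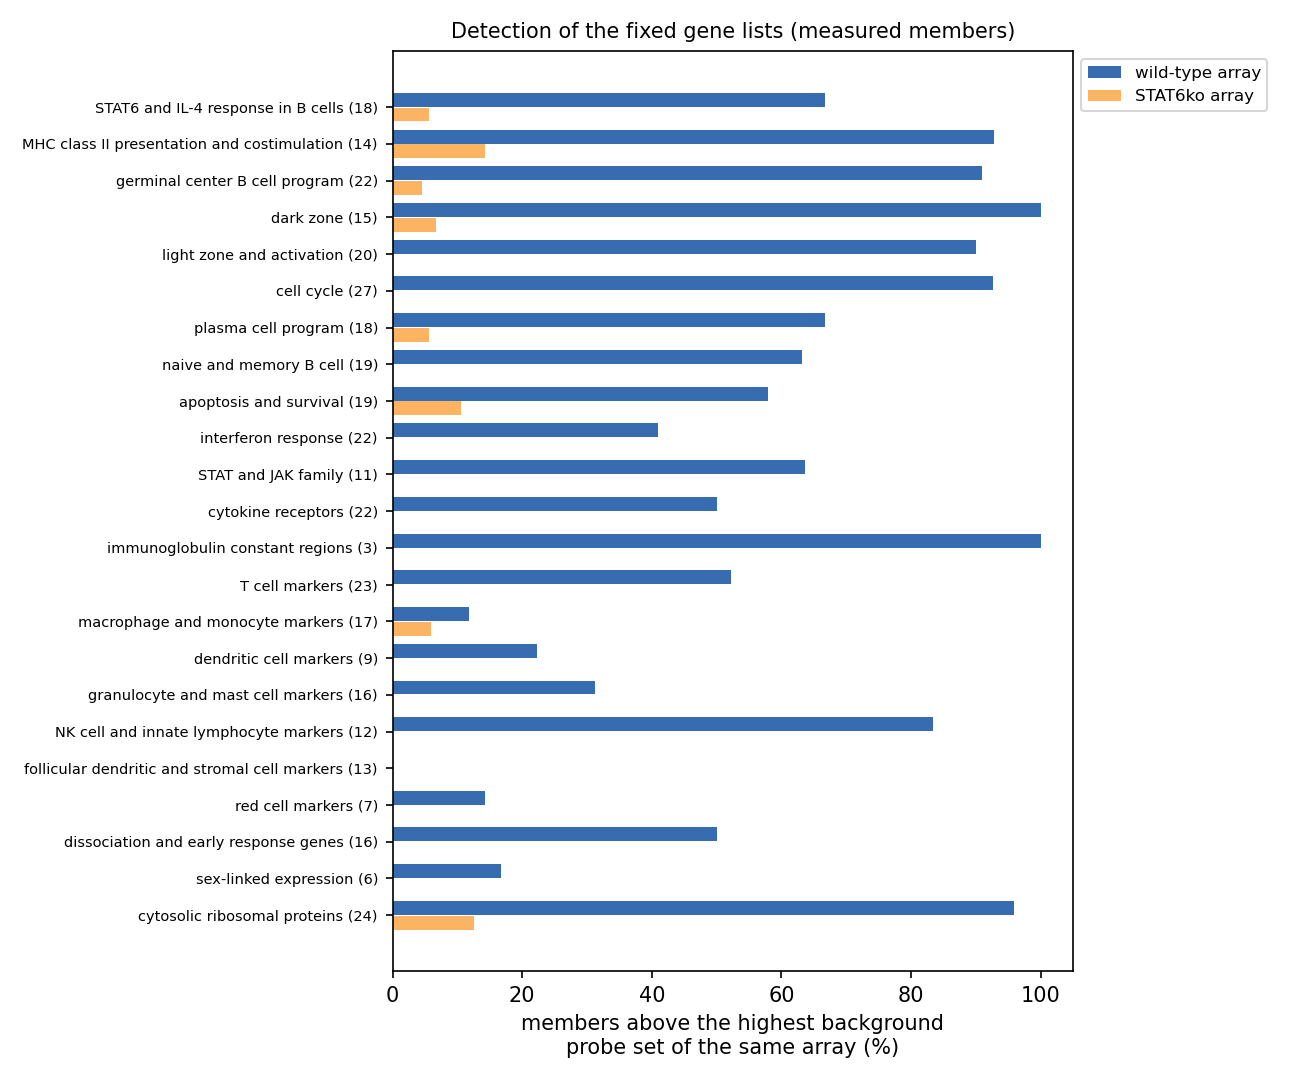
Share of the measured members of each fixed gene list (number in brackets) above the highest background probe set of the same array, in percent, on the wild-type and the STAT6ko array, 1 array each. The wild-type bars reach 100% for the 15 dark zone genes and the 3 immunoglobulin constant region genes and are empty for the 13 stromal markers, and the STAT6ko bars rest on at most 3 genes in any list.

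Among sex-linked genes Xist, the RNA of X inactivation in females, read 8.99 on the wild-type array, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not above background on either array. Eif2s3y read 2.76 on the STAT6ko array and 1.06 on the wild-type array, and this list lay at percentile 99.9 of matched random lists. Its median difference was 1.15 and its mean difference -0.03, since Xist read 2.80 on the STAT6ko array.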

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

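The tests on the array controls, on the share of probe sets above background, on the background probe sets and on genes of other chromosomes were chosen after the result was seen; those on genes near the loci, other cell types and the share of low-level genes were planned.

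Of the 5991 mouse probe sets with no gene symbol, which enter no comparison above, 45 were above background on the STAT6ko array and brighter there than on the wild-type array, and 39 of these were not above background on the wild-type array. The brightest read 4.98 and 1.53. As a share of the 5991 sets the 45 are below the 1.23% that exchangeable background values would give above the limit. The count therefore does not show raised transcripts.

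For the near-complete loss of mouse transcript signal on the STAT6ko array, a complete failure of hybridization, staining or scan is argued against by the hybridization controls. All 18 of these sets were above background on that array. Their median difference of 1.63 in its favour does not measure the strength of staining or scan, because RMA signals are rescaled. Loss of STAT6 in the cells as the whole cause is argued against by the share of mouse probe sets above background, 1.19% against 1.23% by chance. The labels give 200 ng of total RNA for either array. RNA labelled as on the wild-type array should light up far more transcripts than the few that were bright, such as Atox1 (10.55) and Rpl41 (9.92). Little or no labelled target made from the RNA is a candidate explanation that goes with the poly-A controls, whose median difference was -9.15. It stays a hypothesis, because the labels do not say that these controls were added to both samples, and a biological difference between the fractions could lie beneath it unmeasured. The labelling kit named in the labels does not match the array, but it is named for the wild-type array too, and neither this nor a deposit of another array than the one the study used was tested.

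Among the genes that differed 2-fold, the background probe sets could not decide on noise near background for those dimmer on the STAT6ko array. Of the 80 sets 0 (exact 95% binomial interval up to 4.51%) were as much dimmer there, against 24.0% of all genes. These sets had a 95th percentile of 1.58 on the wild-type array and the lower quartile of the STAT6ko array was 1.22, so few could fall 2-fold. Of the 4956 dimmer genes 4924 were above background on the wild-type array, so their signal there exceeded that of the background sets. The threshold itself largely fixed this count. A gene at the STAT6ko lower quartile of 1.22 passes the wild-type limit of 2.08 whenever it is 2-fold dimmer. The count therefore does not decide on noise either. For the genes brighter on the STAT6ko array values near background are a likely source, because 17 of the 80 background sets (21.25%) passed the same threshold, against 9.33% of all genes. The 2 shares are of unlike levels, because all genes include 7004 above background on the wild-type array, which hold 38 of the 1928 brighter genes. The background sets also had a higher median on the STAT6ko array (1.40) than on the wild-type array (1.04). Noise therefore cannot be told apart from this offset of low values. The planned measure, the 7.98% of changed genes in the lowest of 3 equal groups by mean level, decided nothing, because the mean holds the difference itself and keeps dimmer genes out of that group. Linked DNA of other strains around Stat6 or Ptprc is argued against as the whole cause, since 88.6% of changed genes lay on other chromosomes, and for the 2.42% within 20 Mb of either locus, against 2.33% of all genes tested (Fisher's exact test, one-sided, p = 0.281), it cannot be told apart from the loss of signal. Cells of another type in one fraction stay open too, because 0 of 7 lists of such markers lay outside the central 95% of random lists but an array at background cannot show them.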

How the results depend on the processing

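The restriction to genes above background on both arrays, the lower background limit and detection by any probe set were tested after the result was seen.

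The count of brighter genes on the STAT6ko array, 1928 as reported, was 4036 at 1.5-fold, 716 at 3-fold, 1115 with the mean over a gene's probe sets, 4225 after quantile normalization and 3 with the pseudocount. The count of dimmer genes, 4956, was 2877 after quantile normalization, 2256 after removal of the intensity trend and 1495 with the pseudocount. Among genes above background on both arrays, a filter added after seeing the data, 27 were brighter and 111 dimmer. Dropping the floor moved neither count, since every gene past 2-fold already passed it, and the second deposited table holds the same values. The background limit at its 95th percentile, also added later, raised genes above background from 404 to 1612 on the STAT6ko array and from 7004 to 9326 on the wild-type array, where list members above background went from 9 to 16 for the interferon response, 2 to 5 for macrophages, 0 to 3 for stromal cells, 1 to 2 for red cells and 12 to 18 for T cells. Counting a gene by any of its probe sets gave 451 and 7125 genes, 13 T cell markers and 8 STAT and JAK genes, and moved no other list on the wild-type array. The Stat6 difference, with a STAT6ko value at background, was -0.14 with the pseudocount and -0.65 over both probe sets. The median of the interleukin-4 list stayed negative in all 7 alternatives, at -1.95 with the mean over probe sets, -0.89 after quantile normalization, -0.26 without the trend and -0.70 with the pseudocount. Signs turned as follows, and apart from the choice of probe set the cause was not tested. With the mean over probe sets, Atox1 came to -0.014 and Eif4e to -0.19. After quantile normalization, with probe sets chosen anew, the plasma cell list came to 0.053, the naive and memory list 0.043 and the cytokine receptor list 0.068. Xbp1 came to 0.052 and Tnfrsf13b to 0.058. Nt5e (2.76), Stat3 (4.45) and Tgfbr2 (3.52) were read there by another probe set than above, since a rescaling that keeps ranks cannot turn their first sets. Without the trend the plasma cell list came to 0.34, the apoptosis list 0.24, the early response list 0.013, Batf3 -0.081, H2-Aa 2.20, H2-Ab1 0.64, Nfkbia 0.76, Xbp1 1.62, Cr2 1.04, Mcl1 0.24, Bid 0.84, Casp8 0.67, Tnfrsf13b 1.12, Lck 1.21, Tcrb-J 0.36, Cd3d 0.27, Dnajb1 0.27 and Xist 0.072. No scaling moved the median of all genes by over 0.1. No paired analysis was possible because each group has 1 array, and no replicate could be left out for the same reason. Signal over background on the STAT6ko array leaves at most a bound on the ratio for the 6742 genes above background on the wild-type array alone.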

Other observations

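The test on T cell markers was chosen after the result was seen.

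Genes above background on both arrays numbered 262, against 137 if the 2 sets were independent (320 and 156 counting any probe set of a gene). Among the brightest of them on the STAT6ko array, named after their values were seen, were Atox1, Rpl41, a ribosomal protein gene, at 9.92 (10.74 on the wild-type array), Rbx1, a subunit of cullin ubiquitin ligases, at 7.51 (7.45), Morf4l1, a chromatin protein, at 6.76 (7.27) and Hnrnpab, an RNA-binding protein, at 5.64 (6.54). Other abundant transcripts read low beside them, for example Rpl4 (1.46 against 10.15).

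The T cell transcripts on the wild-type array were weighed as well. T cells, or RNA from them, in the sorted fraction are a possible explanation, although the B220 gate should remove T cells. Of the 23 markers 52.2% were above background, against 0% of the stromal markers (18 of 23 and 3 of 13 at the lower background limit), 83.3% of the NK cell and innate lymphocyte markers and 33.9% of all genes, and Cd3d (4.96), Cd3g (3.50), Cd3e (3.51) and Icos (3.84) were among them. Cd4 (1.73), Cd8a (1.64) and the set annotated Tcra (1.98) were not, so the test left the explanation open. Cd28, 1 of the 23, is also on the plasma cell list, and some B cells express Cd2 and Cd5.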
